A study of Mus musculus with 10 samples.

How the data were processed

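Bulk mRNA was measured in 9 libraries, 3 each of R1 from blood and of R2′ and R3′ from inflamed synovium, and a targeted single-cell library in 1 sample of CX3CR1hi Ly6Cint cells. Per the labels, RNA was extracted with TRIzol and bulk libraries were made with a stranded mRNA kit. Per the submitters' processing notes, the authors used TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cuffnorm 2.2.1 with mm10. The gene annotation, the scaling option of Cuffnorm, the digestion of the tissue and the calling of cells are not given in the sources used here. The deposited bulk values are FPKM, 1 file per library, as the Cuffnorm note and the values themselves show. The deposited single-cell values are counts of molecules per cell and amplicon after a correction of molecular identifiers that the name of the deposited file gives as DBEC, with 1 column per amplicon. The values were whole numbers and were not normalized.

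FPKM totals ran from 540472 to 674351 per library, which is no depth. A relative depth of each library was estimated from the most frequent ratio of low values between libraries, and only 8.37% to 14.4% of those genes shared that ratio, so it is rough. Of 23284 gene symbols, 20873 matched 1 gene of GENCODE vM21 (GRCm38, the assembly of mm10), from which coordinates were taken. The genes Chil3, Adgre4, Adgre1, Pkm and Hbb-bs of the gene lists appear under the older symbols Chi3l3, Emr4, Emr1, Pkm2 and Beta-s, and Ly6g and Hbb-bt were not matched.

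Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested (10958 genes). limma 3.58.1 in R 4.3.3 fitted all 9 libraries together on log2 of FPKM plus 1, with a mean-variance trend, 6 residual degrees of freedom and no covariate, and tested R2′ against R1, R3′ against R1 and R3′ against R2′. The labels do not say what a replicate number marks. Deviations from the group means correlated above 0.1 in all 3 same-numbered pairs of R1 and R2′ (0.105 to 0.212, other pairs at most 0.0642). Deviations from a mean of 3 libraries sum to 0, so high values in these pairs lower the other pairs, which are no separate evidence. The number is taken as a pairing for R2′ against R1, from the data alone. Whether it also pairs the R3′ libraries is left open, and the main fit holds no block for it. Tests were two-sided, with Benjamini-Hochberg adjustment within each contrast and calls at an adjusted p under 0.05. Because 1 is added to every FPKM, differences of genes near 0 are understated. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so none was run per gene. On simulated data for R3′ against R1 with 10958 genes, the fit recovered 89% of 100 genes changed by log2 1 and 99% of 100 genes changed by log2 2, and called 8 unchanged genes.

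25 gene lists were written before the data were examined, of which 10 hold markers of other cell types. limma camera tested each list with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 25 lists of a contrast. Genes named in the text were chosen by a rule also written before the data were examined. The rule takes the 5 called genes with the largest increase and the 5 with the largest decrease per contrast (mean of at least 10 FPKM in the higher group, groups not overlapping), 10 fixed genes, and up to 4 members per list by moderated statistic with a mean of at least 5 FPKM. Exceptions chosen after their values were seen are named in the closing section. Overlap of calls between contrasts was set beside the product of both list sizes over the genes tested and beside 100 simulations of unchanged groups.

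Single-cell counts of 2 genes with 2 amplicons were summed, giving 402 genes, of which 42 had no molecule. All 8682 cells passed the minimum of 200 molecules and 20 genes. Counts scaled to the median total were logged, and scanpy 1.11.5 clustered the cells on 20 principal components with 15 neighbours by Leiden at a resolution of 0.5. Leading genes of a cluster were ranked by fold over the other cells, with 0.1 added to both means. A cluster took the name of a class when at least 3 of its fixed markers were at least 2 times higher, at least 1 of its markers ranked in the top 10, and every other class had fewer markers there. The class of monocytes or macrophages was counted but could not name a cluster. This naming rule, the added 0.1 and an exact search of neighbours were chosen after first looks at the data. Scrublet called no doublets and is not interpreted, since its threshold lay at a score of 0.605. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, and a share of 0 carries the limit of 3 counts of the total. Both cover counting error of cells with a molecule only. For co-detection each cell was thinned to 1202 molecules, the 10th percentile of the totals, and 868 cells below it were left out. Thinning was tested on simulated cells, where shallow and deep cells held Nfatc1 in 56.8% and 92.4% before and 48.0% and 53.6% after it.

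Alternatives covered the pseudocount, the filter on low values, quantile normalization and median centring, the variance model, library weights, a block for the replicate number, fits of 6 libraries, a minimum difference, each library left out, the estimated correlation, thinning, the molecules needed per cell, the doublets and the Leiden resolution. Leaving out small-RNA genes and the 5% of cells with the most molecules were added after seeing the data. Figures were drawn with matplotlib 3.10.9. The reads were not analysed here.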

Results

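The samples are mouse cells from blood and from the inflamed lining of joints (synovium), all called inflammatory monocyte cells in the labels. Bulk mRNA sequencing covered 3 sorted subsets with 3 libraries each, R1 from blood and R2′ and R3′ from synovium. The sorting gates of these subsets are not given in the sources used here. A further sample is a single-cell library of sorted CX3CR1hi Ly6Cint cells, read with a targeted panel of 404 amplicons (BD Rhapsody). Each bulk library lists FPKM (sequenced fragments scaled to gene length and library size) for 23284 genes, of which 6896 stood at 0 in all 9 libraries. The files hold no read counts, so absolute depth is unknown, and the steps between low values place the relative depth between 0.733 (R2′ replicate 3) and 1.28 (R3′ replicate 1) of that of R1 replicate 1. The single-cell library held 22855735 molecules in 8682 cells, with a median of 2366.5 molecules and 118 genes per cell. The labels do not say that replicates are separate animals, so errors and adjusted p-values measure the spread between these libraries only.

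The comparison of R2′ with R1 asks how an inflamed-synovium subset differs from blood cells, with tissue and subset changing together. Of 10958 genes tested with limma, 4531 were called at an adjusted p under 0.05, 2308 higher and 2223 lower in R2′. The share of calls that were higher, 50.9%, fell to 42.0% after quantile normalization and 45.5% after median centring, so which direction held more calls depends on scaling. In 54.2% of the tested genes the FPKM of the 2 groups did not overlap, against 10% by chance. Among the largest increases, Cxcl2 stood at 7.46 ± 11.3 FPKM in R1 and 3282 ± 1166 FPKM in R2′ (SD, n = 3 here and for all bulk values). Spp1 rose from 0.502 ± 0.0630 to 1065 ± 650.2 FPKM, Arg1 from 0.279 ± 0.210 to 761 ± 528 FPKM, and Cxcl1 from 0.157 ± 0.272 to 525 ± 270.0 FPKM. The small-RNA gene Mir22 also ranked among them, but its FPKM is divided by a very short length and is uncertain. The largest decreases were in red cell genes and Nrgn. Hba-a1 fell from 1414 ± 171 to 6.20 ± 1.65 FPKM, Alas2 from 48.0 ± 5.38 to 0.201 ± 0.148 FPKM, and Nrgn from 33.3 ± 16.5 to 0.0995 ± 0.111 FPKM. The globin genes Hba-a1, Beta-s and Hbb-b2 have near-identical copies, which leaves the split between copies uncertain.

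Gene lists fixed in advance described the same contrast. All 15 tested glycolysis and hypoxia genes were higher in R2′ than in R1, with Vegfa 7.63 ± 0.28 (log2 difference ± SE), Tpi1 2.67 ± 0.15, Pfkl 2.15 ± 0.12 and Hif1a 2.32 ± 0.15. Of 19 cytokine and chemokine genes, 18 were higher and 1 lower in R2′, and Il1b rose from 176 ± 12.2 to 3406 ± 315 FPKM, Il1rn from 8.56 ± 2.01 to 559.6 ± 159 FPKM and Il1a from 0.179 ± 0.127 to 62.7 ± 26.6 FPKM. Of 18 macrophage maturation genes, 16 were higher and 0 lower, among them C1qa (log2 4.82), C1qb (3.89) and C1qc (4.18). Of 14 matrix protease and inhibitor genes, 11 were higher and 0 lower, led by Adam8 (5.08), Timp1 (6.69), Mmp14 (5.16) and Plau (3.91). Fibroblasts also express protease and inhibitor genes, and 8 of 8 fibroblast markers were higher in the same R2′ libraries (median log2 3.49). Of 14 lipid-handling genes, 8 were higher and 1 lower. Of 18 immediate early and heat shock genes, 14 were higher and 1 lower, with Egr1 at 5.17 and Fos at 2.81. With limma camera at its preset correlation, the adjusted p of these 6 lists was 8.58e-11 for glycolysis, 8.58e-11 for cytokines, 4.04e-10 for macrophage maturation, 1.02e-06 for proteases, 0.0282 for lipid handling and 2.7e-06 for immediate early genes. With an estimated correlation none of the 6 was called, at an adjusted p of 0.27 for immediate early genes and 0.257 for each of the others. The 1 lower lipid-handling gene became 3 with the replicate number as a block and 2 without R1 replicate 1 or R2′ replicate 3, and the 1 lower immediate early gene became 0 without R1 replicate 1, R1 replicate 2, R2′ replicate 1 or R2′ replicate 2.

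Of 14 antigen presentation genes, 4 were higher and 2 lower in R2′ than in R1, and 8 were not called. The costimulatory genes Cd83 (log2 5.55), Cd80 (3.26) and Cd86 (2.61) were higher in R2′ while the regulator Ciita (-1.50) was lower, and the list was not called (limma camera adjusted p 0.166). The 2 lower became 1 without R1 replicate 1, R1 replicate 2, R2′ replicate 1 or R2′ replicate 3. Of 11 classical monocyte genes, 7 were lower, Hp (-1.42) among them, and 2 higher, Cd14 (5.79) and Itgam (1.15), and the 7 became 4 without R1 replicate 1, R1 replicate 2 or R2′ replicate 3. Of 12 non-classical monocyte genes, 8 were lower, led by Ace (-3.74) and Spn (-2.56), and 3 higher, including Nr4a1 (2.57) and Cd9 (3.00). Neither monocyte list was called, at limma camera adjusted p 0.23 and 0.0663, but the non-classical list was called without R1 replicate 1 (median log2 -2.20) or R2′ replicate 2 (-1.99), against -1.83 with all libraries, and without a filter (-1.74). Of 10 resident synovial macrophage genes, 5 were higher and 0 lower (limma camera adjusted p 0.0663, called without R2′ replicate 2 at a median of 0.63 against 0.53, after quantile normalization at 0.42, after median centring at 0.48, with a pseudocount of 0.1 at 1.32 and without a filter at 0.25; 1 was lower without R1 replicate 3 or R3′ replicate 3), and Sparc, which fibroblasts also express and which is listed at 0 in R1, reached 20.8 ± 12.5 FPKM in R2′, where all 8 tested fibroblast markers were higher than in R1. Proliferation genes did not move together, with 1 mitosis gene higher (Cenpa 1.76) and 3 lower of 21, and 3 DNA replication genes higher and 1 lower of 18 (limma camera adjusted p 0.868 and 0.464). These counts rest on single libraries, since the 3 lower mitosis genes became 0 without R1 replicate 1, R1 replicate 3 or R2′ replicate 2 and 1 without R2′ replicate 3, and the 1 lower DNA replication gene became 0 without R1 replicate 3, R2′ replicate 2 or R2′ replicate 3 and 2 without R3′ replicate 1 or R3′ replicate 3. Without R3′ replicate 3, 2 mitosis and 5 DNA replication genes were higher. Interferon-stimulated genes had 3 higher and 3 lower of 16, and none of 15 oxidative phosphorylation genes was called (limma camera adjusted p 0.909 and 0.849). The 3 higher interferon-stimulated genes became 1 without R1 replicate 2, R1 replicate 3, R2′ replicate 2 or R2′ replicate 3, and 1 oxidative phosphorylation gene was lower without R3′ replicate 3 or with the replicate number as a block.

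The comparison of R3′ with R1 sets the other synovial subset against blood. limma called 6470 genes, 3399 higher and 3071 lower in R3′ (52.5% higher, against 44.7% after quantile normalization and 49.3% after median centring, which turns the majority), and 67.2% of tested genes had groups that did not overlap. Spp1 reached 1685 ± 819 FPKM in R3′, Arg1 848 ± 459.7 FPKM, Cxcl1 452 ± 164 FPKM and Cxcl2 1412 ± 604 FPKM. Cd63 rose from 1.76 ± 1.25 to 713 ± 48.9 FPKM. Plac8 fell from 2909 ± 577 to 8.86 ± 1.37 FPKM and Arhgef37 from 112 ± 9.19 to 0.472 ± 0.170 FPKM. All 21 tested mitosis genes were higher in R3′ than in R1, led by Cdk1 (log2 3.80), Top2a (4.09), Ccna2 (3.61) and Plk1 (2.32). All 18 DNA replication genes were higher, with Mcm6 rising from 0.256 ± 0.0789 to 41.1 ± 15.5 FPKM. All 18 macrophage maturation genes were higher, C1qa rising from 5.62 ± 2.10 to 1593 ± 180.2 FPKM. All 10 resident synovial macrophage genes were higher, with Gas6 rising from 0.0214 ± 0.0186 to 61.3 ± 8.18 FPKM. The limma camera adjusted p was 6.34e-08 for mitosis, 9.9e-08 for DNA replication, 2.43e-09 for macrophage maturation and 3.43e-05 for the resident list, and the adjusted p with an estimated correlation was 0.31 for each of the 4. All 8 tested fibroblast markers were higher in these R3′ libraries too (median log2 2.73).

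Classical monocyte genes were lower in R3′ than in R1 for 10 of 11 members, with Chi3l3 at log2 -4.73, Vcan at -4.26 and Hp at -3.55, while Cd14 was higher at 3.99. Non-classical genes were lower for 8 of 12, led by Ace (-5.73), Emr4 (-5.13), Itgal (-4.31) and Treml4 (-3.82), and higher for 3. Their limma camera adjusted p was 0.000233 and 0.0187, and 0.31 for both with an estimated correlation. Cytokine genes were higher for 18 of 19 and lower for 1, with Ccl7 at 7.49 and Il10 at 4.87. Glycolysis genes were higher for 12 of 15, protease genes for 12 of 14, and immediate early genes for 16 of 18, with none lower (limma camera adjusted p 2.44e-06, 5.27e-06, 3.43e-05 and 0.000233 for the 4 lists in turn, and adjusted p 0.31 for each with an estimated correlation). Lipid-handling genes were higher for 9 of 14 and lower for 3, with Abca1 at 5.81, Fabp5 at 5.98 and Scarb1 at -2.77 (limma camera adjusted p 0.0349, and adjusted p 0.31 with an estimated correlation), and the list was not called with array weights (1.30). Antigen presentation genes were higher for 3 and lower for 6 of 14, with H2-DMa at -2.16 and H2-DMb1 at -1.78 (limma camera adjusted p 0.153). Interferon-stimulated genes were higher for 3 and lower for 7 of 16, with Irf7 at -2.24, and oxidative phosphorylation genes were higher for 7 of 15, with Atp5b at 0.76 (limma camera adjusted p 0.346 and 0.0506). The 3 higher interferon-stimulated genes became 1 without R1 replicate 3, R3′ replicate 2 or R3′ replicate 3, and the 7 lower became 4 without R1 replicate 1, R1 replicate 2 or R3′ replicate 1. The oxidative phosphorylation list was called without R1 replicate 2, R2′ replicate 3 or R3′ replicate 3, at medians of 0.52, 0.44 and 0.51 against 0.44, and also with a pseudocount of 0.1 (0.45) or 5 (0.42), without a filter or with a filter of 5 FPKM (both 0.44), after quantile normalization (0.43) and with array weights (0.42).

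R3′ against R2′ compares both synovial subsets within the same tissue. limma called 5103 genes, 2525 higher and 2578 lower in R3′, with 55.8% of tested genes not overlapping. Proliferation genes separated the subsets. Of 21 mitosis genes 20 were higher in R3′ and 0 lower, and Top2a rose from 1.27 ± 1.24 FPKM in R2′ to 38.1 ± 14.96 FPKM in R3′, Birc5 from 0.684 ± 0.764 to 31.9 ± 14.0 FPKM and Cdk1 from 0.689 ± 0.280 to 17.9 ± 8.19 FPKM. Of 18 DNA replication genes 17 were higher and 0 lower, with Mcm6 at log2 4.37, Uhrf1 at 3.32, Mcm5 at 2.78 and Prim1 at 2.52. The limma camera adjusted p was 1.23e-10 for mitosis and 5.92e-10 for DNA replication, and with an estimated correlation the adjusted p was 0.579 and 0.492. Ccl8 rose from 0.844 ± 1.01 to 119 ± 41.2 FPKM, Cbr2 from 6.80 ± 4.39 to 214 ± 78.0 FPKM, Phyhd1 from 1.22 ± 0.789 to 60.7 ± 7.73 FPKM and Fcrls from 7.94 ± 11.6 to 190.2 ± 148 FPKM. The small-RNA genes Mir1894 and Mir5107 had the largest differences, in opposite directions, and are as uncertain as Mir22.

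Most classical monocyte genes and part of the non-classical ones were lower in R3′ than in R2′, and most macrophage genes were higher. Ly6c2 fell from 155 ± 87.7 to 4.999 ± 1.78 FPKM, Plac8 from 786 ± 482 to 8.86 ± 1.37 FPKM, Vcan from 205 ± 60.0 to 10.2 ± 5.98 FPKM and Ear2 from 32.2 ± 12.9 to 0.788 ± 0.749 FPKM. Ly6c2 codes for Ly6C, which the label of the single-cell sample names for sorting. If the bulk subsets were sorted on it too, its difference only checks the labels. Of 11 classical monocyte genes 10 were lower and 0 higher, and of 12 non-classical genes 6 were lower and 0 higher. Of 10 resident synovial macrophage genes 8 were higher and 0 lower, with Folr2 at log2 4.26, Mrc1 at 2.86 and Vsig4 at 4.17. Of 18 macrophage maturation genes 14 were higher and 1 lower, with C1qa at 3.14, C1qb at 2.40 and Emr1 at 1.20. The limma camera adjusted p of these 4 lists was 3.02e-05, 0.0483, 0.000122 and 7.27e-05, and with an estimated correlation the adjusted p was 0.492, 0.762, 0.492 and 0.728, so that none was called. The non-classical call was lost without R3′ replicate 1 or R3′ replicate 2, where the median log2 difference was -0.86 and -0.76 against -0.90 with all libraries, and also after quantile normalization (-0.76), with a pseudocount of 5 (-0.58), with a filter of 5 FPKM (-0.90) and with array weights (-1.17). Without R1 replicate 1 or R2′ replicate 2, 1 non-classical gene was higher, and without R1 replicate 1 or R1 replicate 2, 2 macrophage maturation genes were lower.

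Part of the antigen presentation, glycolysis and cytokine genes were lower in R3′ than in R2′. Of 14 antigen presentation genes 9 were lower and 0 higher, with H2-DMa at log2 -2.06, H2-DMb1 at -1.77, Cd86 at -2.51 and Cd80 at -2.16. Of 15 glycolysis genes 8 were lower and 0 higher, and Vegfa fell from 307 ± 27.2 to 70.3 ± 2.88 FPKM and Slc2a1 from 211 ± 55.3 to 73.7 ± 17.9 FPKM. Of 19 cytokine genes 7 were lower and 0 higher, and Il1b fell from 3406 ± 315 to 892 ± 358 FPKM. Oxidative phosphorylation genes went the other way, 8 of 15 higher and 0 lower, by 0.55 for Ndufa9 and 0.72 for Cox5a on the log2 scale. The limma camera adjusted p of the 4 lists was 0.000884, 0.000884, 0.0296 and 0.00561, and with an estimated correlation the adjusted p was 0.492, 0.762, 0.767 and 0.767, so that none was called. The cytokine call was lost without R2′ replicate 1, R2′ replicate 3 or R3′ replicate 2, with medians of -0.57, -0.61 and -0.68 against -0.89, and after quantile normalization (-0.85), with a filter of 5 FPKM (-0.54) and with a pseudocount of 0.1 (-1.06). The 8 higher oxidative phosphorylation genes became 5 without R2′ replicate 3, R3′ replicate 1 or R3′ replicate 2, and 1 antigen presentation gene was higher without R3′ replicate 2. Proteases went both ways, 5 higher and 4 lower of 14, with Timp2 at 3.77, Ctsb at 1.77, Mmp19 at -2.75 and Plaur at -1.99. Lipid-handling genes had 6 higher and 5 lower of 14, with Fabp5 at 3.21 and Olr1 at -1.60. Immediate early genes had 1 higher and 6 lower of 18, and interferon-stimulated genes 1 higher and 2 lower of 16. Those 4 lists were not called (limma camera adjusted p 0.885, 0.736, 0.523 and 0.219), apart from the interferon list without R2′ replicate 1, at a median of -0.76 against -0.54. The 6 lower immediate early genes became 3 without R2′ replicate 1 or R3′ replicate 1 and 2 without R2′ replicate 3 or R3′ replicate 2, and the 1 higher became 2 without R1 replicate 1 or R1 replicate 3 and 3 without R2′ replicate 3. The 2 lower interferon-stimulated genes became 6 without R2′ replicate 1 and 1 without R2′ replicate 2, R3′ replicate 1 or R3′ replicate 3, and the 1 higher became 0 without R2′ replicate 2, R2′ replicate 3 or R3′ replicate 1. The 5 higher protease genes became 3 without R3′ replicate 2.

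**Figure D1:**
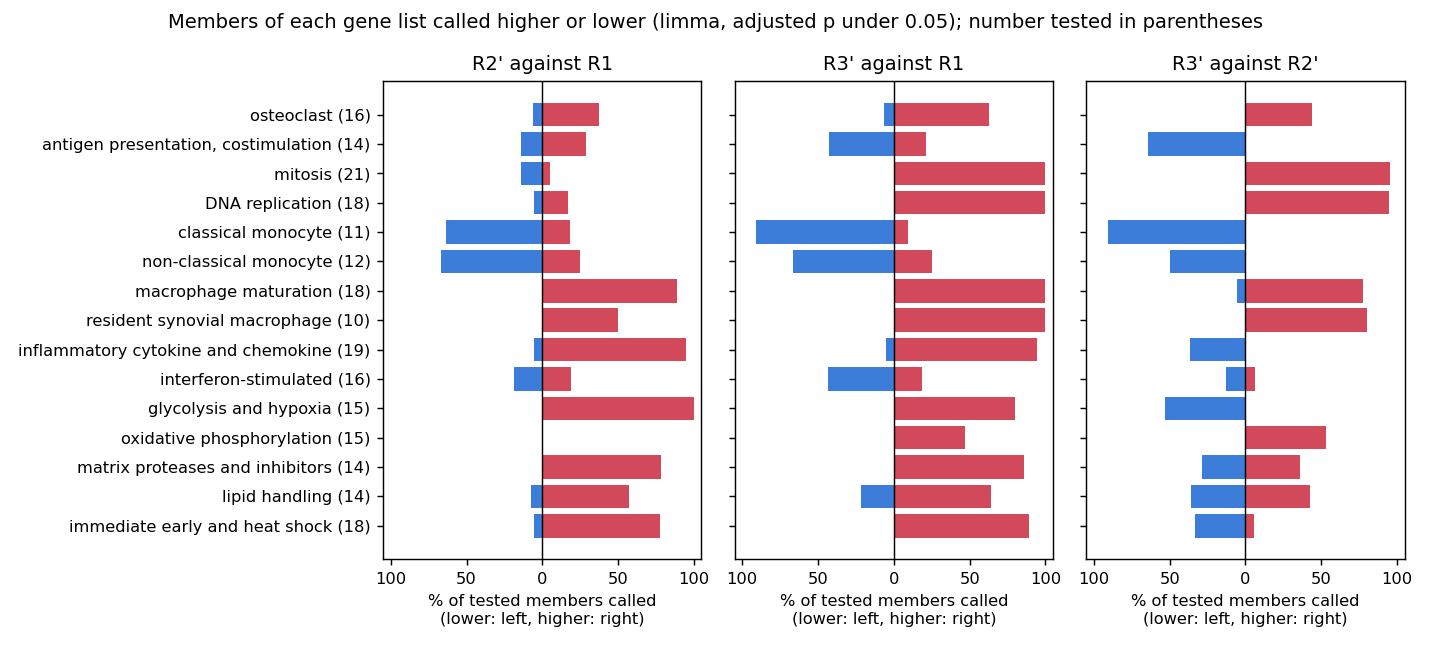
Percent of the tested members of each gene list that limma called higher (right, red) or lower (left, blue) in the first-named group, with the number of tested members in parentheses and 1 panel per contrast. Of the 21 mitosis genes, 20 were higher in R3′ than in R2′ and 1 was higher in R2′ than in R1.

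No list in any contrast kept an adjusted p under 0.05 when limma camera estimated the correlation between its members, and the smallest such values were 0.257 for R2′ against R1, 0.31 for R3′ against R1 and 0.492 for R3′ against R2′. That test rests on 6 residual degrees of freedom and has little power, so a call lost in it does not show that a list is unchanged. Counts of members adjusted over the list alone differed from those over all genes by at most 3 in either direction for every list. Osteoclast genes, for example, had 8 higher and 1 lower of 16 in R2′ against R1 adjusted over the list alone, against 6 and 1 over all genes, and mitosis genes had 0 lower in place of 3.

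Foxm1, the gene named in the series title (chromosome 6, 128362967 to 128376146, GRCm38, GENCODE vM21), was low in R1 at 0.766 ± 0.204 FPKM and in R2′ at 0.657 ± 0.0971 FPKM, and reached 8.07 ± 3.16 FPKM in R3′. The 3 R3′ libraries measured 11.1, 8.30 and 4.81 FPKM. The log2 difference of R3′ was 2.39 ± 0.24 from R2′ (limma adjusted p 0.000115) and 2.30 ± 0.24 from R1 (limma adjusted p 4.13e-05), while R2′ and R1 differed by -0.09 (limma adjusted p 0.802).

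Osteoclast genes of the single-cell panel were highest in R3′ for Acp5, Ctsk and Atp6v0d2. Acp5 (chromosome 9, 22126727 to 22135711) measured 11.2 ± 2.28 FPKM in R1, 43.2 ± 2.92 FPKM in R2′ and 459.7 ± 331 FPKM in R3′. Ctsk (chromosome 3, 95499256 to 95509362) measured 1.12 ± 0.805, 15.4 ± 1.501 and 492 ± 359.7 FPKM in the same order. Atp6v0d2 (chromosome 4, 19876841 to 19922605) measured 0.0254 ± 0.0440, 1.60 ± 0.607 and 66.9 ± 48.8 FPKM. R3′ exceeded R2′ by log2 3.01 ± 0.54 for Acp5 (limma adjusted p 0.00195), 4.58 ± 0.53 for Ctsk (limma adjusted p 0.000213) and 4.42 ± 0.50 for Atp6v0d2 (limma adjusted p 0.000179). R2′ exceeded R1 for Acp5 (1.88, limma adjusted p 0.0207) and Ctsk (3.01, limma adjusted p 0.00174), and for Atp6v0d2 by 1.31 without passing the threshold (limma adjusted p 0.0593), which it passed at 1.31 with the replicate number as a block. The Acp5 call in R2′ was lost without R1 replicate 2 (log2 1.74) or R2′ replicate 3 (1.82). The R3′ libraries spread widely, with 780, 480 and 119 FPKM for Acp5. Without R3′ replicate 1 the log2 difference from R2′ was 2.44 for Acp5 and 3.86 for Atp6v0d2, and without R3′ replicate 3 it was 3.79 for Acp5, 5.28 for Ctsk and 5.09 for Atp6v0d2.

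Nfatc1 (chromosome 18, 80606205 to 80713071) was not called in any contrast, at 39.1 ± 4.18 FPKM in R1, 65.6 ± 4.96 FPKM in R2′ and 73.6 ± 36.2 FPKM in R3′. Itgb3 (chromosome 11, 104608000 to 104670476), which platelets also express, was highest in blood at 6.79 ± 1.22 FPKM, against 0.386 ± 0.284 FPKM in R2′ and 2.59 ± 1.89 FPKM in R3′. Its log2 difference of R3′ from R2′, 1.21 (limma adjusted p 0.0321), was lost without any of R2′ replicate 1, R2′ replicate 3, R3′ replicate 1 or R3′ replicate 2, at 1.20, 1.07, 0.86 and 1.03. Tnfrsf11a, which codes for the RANK receptor, was higher in both synovial subsets, at 24.99 ± 10.7 FPKM in R2′ and 25.7 ± 8.83 FPKM in R3′ against 2.69 ± 0.262 FPKM in R1. Csf1r measured 504 ± 21.7 FPKM in R1, 599 ± 20.7 FPKM in R2′ and 417 ± 51.6 FPKM in R3′, and its decrease from R2′ to R3′ was called by limma (log2 -0.53, adjusted p 0.00535) but not after quantile normalization, at -0.31. Cx3cr1, whose protein the label of the single-cell sample names for sorting, did not differ detectably, at 30.7 ± 14.2, 32.8 ± 8.51 and 38.2 ± 14.6 FPKM.

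Across the whole osteoclast list, R3′ against R2′ had 7 of 16 genes higher and 0 lower (limma camera adjusted p 0.0214, and adjusted p 0.767 with an estimated correlation), among them Mitf at log2 0.86, and the list was no longer called without R3′ replicate 1, where its median fell to 0.34 from 0.48. R3′ against R1 had 10 higher and 1 lower (limma camera adjusted p 0.00525, and adjusted p 0.366 with an estimated correlation), and 0 lower without R1 replicate 3. R2′ against R1 had 6 higher and 1 lower, including Mitf (1.25) and Prdm1 (2.38) higher and Itgb3 lower (limma camera adjusted p 0.0531). That list was called without R1 replicate 1 (median 1.11), R2′ replicate 2 (0.96), R3′ replicate 1 or R3′ replicate 3 (both 0.92, as with all libraries), and with the replicate number as a block (0.92), a pseudocount of 0.1 (1.07), no filter (0.49), quantile normalization (0.85), median centring (0.88), array weights (0.89), no small-RNA genes or the 6 libraries alone (both 0.92).

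**Figure D2:**
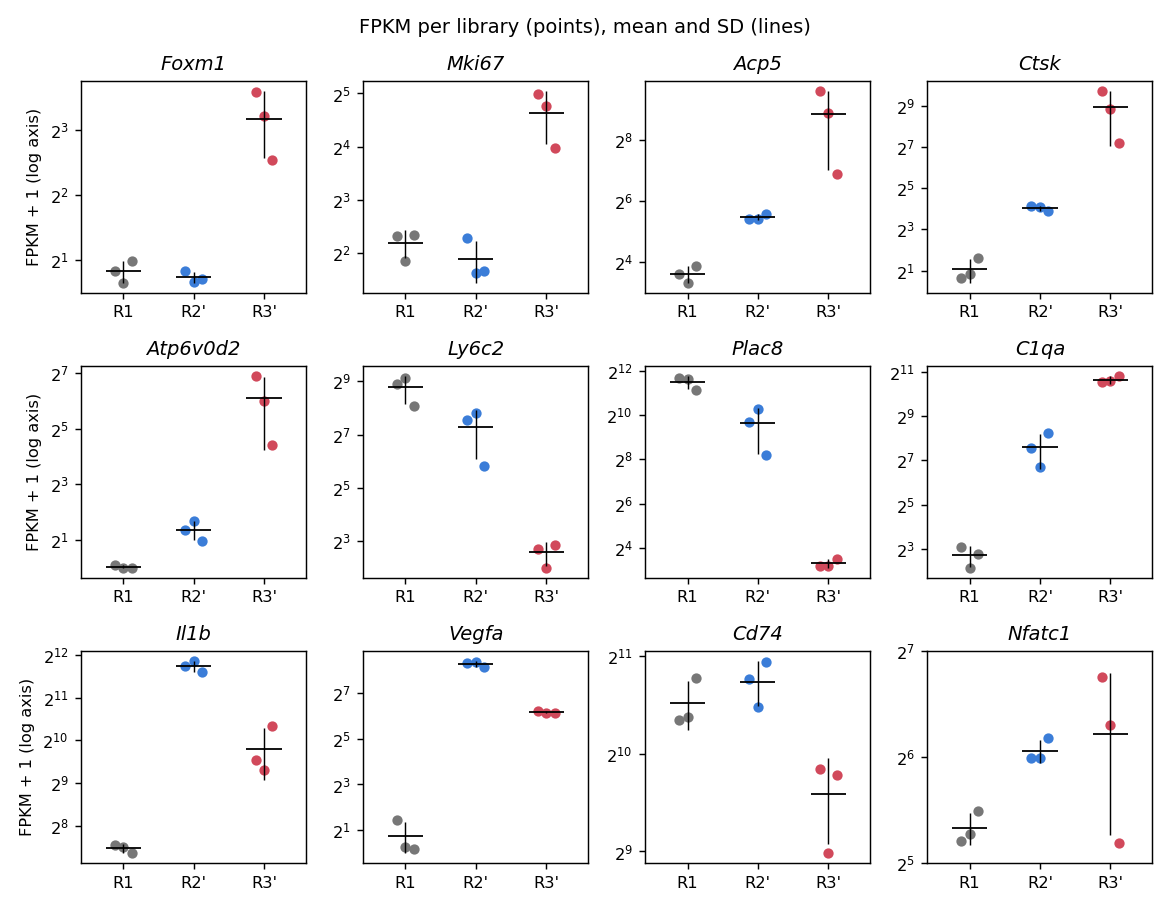
FPKM plus 1 on a log axis for 12 genes, with 1 point per library, the mean as a horizontal line and the SD as a vertical line for R1, R2′ and R3′ (n = 3 each). Foxm1 lies at 4.81 to 11.1 FPKM in the R3′ libraries, and Acp5 spans 119 to 780 FPKM in them.

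The 2 contrasts against R1 shared 3173 genes called in the same direction, 1579 higher and 1594 lower in both synovial subsets. Independent lists of these sizes would share 1338.91 genes, and simulated groups with no effect against the same R1 libraries shared 0 genes at most in 100 draws. That value is chance with no effect in either contrast and gives no level for contrasts that each hold many called genes, and the product of list sizes leaves the shared controls out. The 3 R1 libraries are too few to divide between the contrasts, so part of the excess may come from these shared controls. In opposite directions, 88 genes were higher in R2′ and lower in R3′ than in R1, and 69 were lower in R2′ and higher in R3′, fewer than the 646.82 and 689.54 of independent lists.

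Marker lists of other cell types were read in the same fits. Of 6 tested red cell and platelet markers, 5 were lower in R2′ than in R1, and 5 lower and 1 (Pf4) higher in R3′ (limma camera adjusted p 9.84e-05 and 0.00395, and adjusted p 0.257 and 0.31 with an estimated correlation). The call for R3′ was lost without R1 replicate 1 or R1 replicate 3, although the median log2 difference moved from -4.11 to -5.48 and -5.55. Without any single R1 library the filter kept 4 of these markers, of which 3 were lower in R2′, and in R3′ 2 were lower without R1 replicate 1 and 3 without R1 replicate 2 or R1 replicate 3. Fibroblast markers were higher in R2′ and in R3′ than in R1 for 8 of 8 genes (limma camera adjusted p 2.09e-05 and 0.00197, and adjusted p 0.27 and 0.31 with an estimated correlation). Pdpn measured 183 ± 47.4 FPKM in R2′ and 112 ± 52.1 FPKM in R3′, Col1a1 19.5 ± 13.5 and 7.16 ± 2.05 FPKM, and Col3a1 28.9 ± 25.5 and 13.6 ± 1.32 FPKM, and whether fibroblasts or the sorted cells made these transcripts was not tested. Dendritic cell markers were lower in R2′ and in R3′ than in R1 for 3 of 3 genes, with Batf3 at log2 -2.45 and -3.49 (limma camera adjusted p 0.0224 and 0.0142, and adjusted p 0.27 and 0.31 with an estimated correlation), and the R2′ call was also lost with a filter of 5 FPKM (median -2.08). B-cell markers were lower for 3 of 3 in R2′ and 2 of 3 in R3′, and NK-cell markers for 1 of 1 in each (limma camera adjusted p 0.0282, 0.136, 0.166 and 0.218). The B-cell call in R2′ was lost with an estimated correlation (adjusted p 0.257) and without R1 replicate 2 or R1 replicate 3, at medians of -1.93 and -1.77 against -1.15, or with a filter of 5 FPKM (-1.95). Without a filter the NK-cell list was called lower in R2′ (-1.09) and in R3′ (-1.03), and the B-cell list in R3′ (-0.36). Without any single R1 library the NK-cell marker was not tested, and 1 of 2 tested B-cell markers was lower in R3′. The NK-cell marker thus passed the filter only through the R1 libraries. Its lower values in the filtered synovial data were fixed in advance and carry no information. T-cell markers were higher for 1 of 3 in R2′ and 2 of 3 in R3′, Il7r in both and Cd4 in R3′, where Cd4 reached 8.88 ± 5.25 FPKM (limma camera adjusted p 0.464 and 0.317). The list holds 10 genes, and Cd3d, Cd3e, Cd3g, Lck and Cd5 were too low to be tested. Cd3e and Lck measured at most 0.0697 and 0.119 FPKM in the synovial libraries. In R1 they measured at least 0.426 and 0.240 FPKM, while Cd3d, Cd3g and Cd5 overlapped. The 2 higher genes therefore do not show more T cells in synovium. Without any single R3′ library 2 T-cell markers were tested and 1 was higher in R3′, and 1 was lower there without R1 replicate 1, R2′ replicate 1, R2′ replicate 3 or R3′ replicate 3.

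Neutrophil markers were lower for 3 of 11 in R2′ and both higher and lower for 2 each in R3′ than in R1 (limma camera adjusted p 0.0282 and 0.388), and the R2′ call was lost with an estimated correlation (adjusted p 0.487) and without R1 replicate 1, R1 replicate 3, R2′ replicate 2 or R2′ replicate 3, at medians of -1.15, -1.69, -0.93 and -1.14 against -1.03, and with array weights (-1.04). The 3 lower in R2′ became 6 with the replicate number as a block and without R1 replicate 2 or R2′ replicate 1. Cxcr2 reached 57.2 ± 32.8 FPKM and S100a9 2679 ± 661 FPKM in R3′, against 12.1 ± 9.39 and 1081 ± 1019.7 FPKM in R1. The call of S100a9 in R3′ (log2 1.79) was lost without R1 replicate 2 (1.01), R1 replicate 3 (1.79), R2′ replicate 3 (1.79), R3′ replicate 1 (1.91), R3′ replicate 2 (1.86) or R3′ replicate 3 (1.60), and with a robust variance model, without a filter or with the 6 libraries alone, each at 1.79. Endothelial markers were higher for 1 of 3 in R2′, and 2 higher and 1 lower in R3′ (limma camera adjusted p 0.436 and 0.388), counts that fell to 0 higher in R2′ without R2′ replicate 3, R3′ replicate 2 or R3′ replicate 3, to 0 higher in R3′ without R3′ replicate 2 or R3′ replicate 3, to 1 higher in R3′ without R2′ replicate 3 or R3′ replicate 1, and to 0 lower in R3′ without any single R1 library, R3′ replicate 1 or R3′ replicate 2. The single tested cartilage, bone and muscle marker was higher and the single mast cell and basophil marker lower in both (limma camera adjusted p 0.227 and 0.388, and 0.124 and 0.155), and the latter was not tested without any single R1 library. The mast cell and basophil marker thus passed the filter only through the R1 libraries, so its direction was fixed in advance. Between R3′ and R2′ no marker list was called, the smallest limma camera adjusted p being 0.188 for fibroblasts, whose list was called lower in R3′ without R2′ replicate 2 (median -1.01 against -0.72) and with array weights (-1.24).

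In the single-cell library, 499 of 8682 cells held a Foxm1 molecule, a share of 5.75% with an exact binomial 95% interval of 5.27% to 6.26%. Intervals cover counting error in this 1 library only, and no p-value is given. Acp5 was found in 80.4% of cells, Ctsk in 79.4%, Atp6v0d2 in 30.9%, Nfatc1 in 25.4%, Itgb3 in 10.4% and Cx3cr1 in 8.996%. The panel holds no Ly6c2, Csf1r or Tnfrsf11a. Lyz2 was found in 100% of cells, Itgam in 98.1% and Cd14 in 97.2%. Cd3e and Cd3g were found in 0 of 8682 cells, which allows a share of cells with a molecule of up to 0.0346% (3 counts of the total) and sets no limit on expression, since nothing in this library shows that the panel detects these genes.

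Clustering gave 9 groups of cells, of which 4 met the naming rule for a class. The osteoclast-like cluster held 622 cells (7.16%), led by Mmp9, Itgb3, Ctsk, Acp5 and Atp6v0d2. The proliferating-like cluster held 594 cells (6.84%), led by 2810417H13Rik, Ube2c, Top2a, Mki67 and Aurkb. The dendritic cell-like cluster held 149 cells (1.72%), led by Ccr7, Il1r2, Flt3, Cd7 and Dpp4, and the neutrophil-like cluster 59 cells (0.680%), led by S100a8, Cxcr2 and S100a9. Ccr7 and Itgae, which with Flt3 named the dendritic cell-like cluster, were found in 33 and 71 of all 8682 cells. Each was thus absent from most of its 149 cells. The 5 other clusters are given by number. The rule could not name a cluster after monocytes or macrophages, so a number does not mean that such markers were missing. Cluster 0 (2041 cells) was led by Cxcl13, C1qa, C1qb, Mgst1 and Nrp1, cluster 1 (1573 cells) by Cxcl1, Egr1, Cxcl2, Rgs1 and Fosb, and cluster 2 (1141 cells) by Fn1, Chil3, Arg1, Spp1 and Clec4e at less than 2 times the level of other cells. Cluster 3 (1964 cells) was led by H2-Aa, Cd74, H2-Eb1, H2-Ab1 and Cxcl9, and cluster 5 (539 cells) by Cxcl1, Il1a, Cxcl2, Tnf and Egr1. At a resolution of 0.25 the proliferating-like cells were no separate cluster, and 1209 cells (13.9%) formed the osteoclast-like cluster.

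Free RNA may contribute to these shares and was not measured. In the neutrophil-like cells, with a median of 744 molecules, 49.2% held Acp5, 71.2% Ctsk and 20.3% Atp6v0d2. Per 1000 molecules, Acp5 stood at 1.52 in the neutrophil-like cells, at 1.18 to 2.35 in clusters 0, 1, 2, 3 and 5, at 84.9 in the proliferating-like and at 188 in the osteoclast-like cells, which it helped to define. Ctsk stood at 2.07, 1.49 to 2.64, 95.2 and 288.9 in the same order, and Atp6v0d2 at 0.381, 0.211 to 0.271, 16.2 and 31.9. The dendritic cell-like cells, with a median of 1435 molecules, held 1.36 of Acp5, 0.566 of Ctsk and 0.0906 of Atp6v0d2. In the 5 numbered clusters these genes were thus near the neutrophil-like level, though Ctsk and Atp6v0d2 were above the dendritic cell-like level and Acp5 in cluster 3 above both, so low expression there cannot be separated from background. Nfatc1 stood at 3.54 in the proliferating-like and 3.23 in the osteoclast-like cells, against 0.1003 in the neutrophil-like cells, 0.466 in the dendritic cell-like cells and 0.0503 to 0.121 in the 5 numbered clusters.

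Foxm1 was found in 48.7% of proliferating-like cells (95% interval 44.6% to 52.8%) and 12.7% of osteoclast-like cells (10.2% to 15.6%). It was found in 1.40% to 2.01% of the cells of clusters 0, 1, 2, 3 and 5, in 1.69% of neutrophil-like cells (1 of 59) and in 0 of 149 dendritic cell-like cells, which allows a share of cells with a molecule, not of cells expressing it, of up to 2.01% (3 counts of the total). The neutrophil-like share rests on 1 cell (interval 0.0429% to 9.09%) and sets no level of background, so whether the shares in the 5 numbered clusters are background or low expression is left open. With every cell thinned to 1202 molecules, the shares were 42.7% of proliferating-like and 5.03% of osteoclast-like cells, against 0.787% to 1.05% in the 5 numbered clusters. Of the 499 cells with Foxm1, 289 (57.9%) were proliferating-like and 79 (15.8%) osteoclast-like. Cx3cr1, whose protein the cells were sorted on, was found in 0.161% of osteoclast-like cells.

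At 1202 molecules per cell, cells with Foxm1 (296) carried the osteoclast genes more often than cells without it (7518). Atp6v0d2 was found in 74.0% (68.6% to 78.9%) against 22.8% (21.9% to 23.8%), and Nfatc1 in 74.0% against 16.8%. Acp5 was found in 90.5% against 66.6%, Ctsk in 86.5% against 65.0%, and Itgb3 in 22.3% against 8.82%. Mki67 was found in 65.9% against 2.58% and Top2a in 65.9% against 3.34%. Within the proliferating-like cluster (206 cells with and 276 without Foxm1) the osteoclast genes differed little. Acp5 was at 98.1% and 98.9%, Ctsk at 90.8% and 93.8%, Atp6v0d2 at 87.4% and 87.3%, Itgb3 at 19.9% and 24.3%, and Nfatc1 at 90.8% and 83.7%, with overlapping intervals for all 5 osteoclast genes. Mki67, at 89.3% and 32.2%, and Top2a, at 88.3% and 39.1%, still differed there. Thinning left out 18.9% of proliferating-like and 4.18% of osteoclast-like cells, and all but 4 of the 59 neutrophil-like cells.

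**Figure D3:**
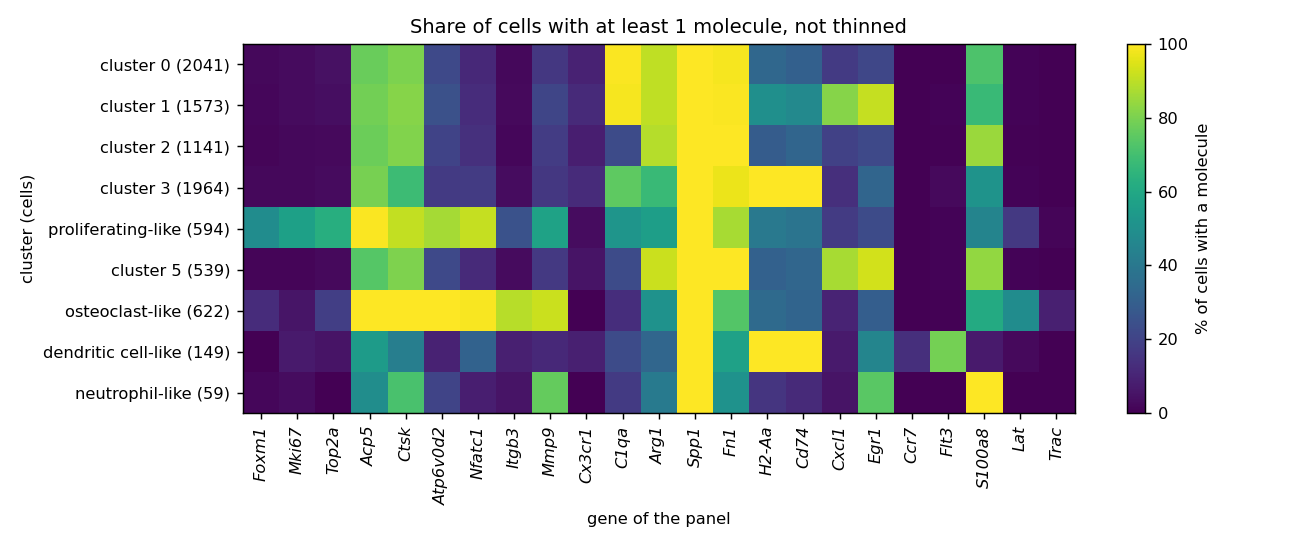
Share of cells with at least 1 molecule, in percent, for panel genes (columns) in the 9 clusters of the single-cell library (rows, number of cells in parentheses), not thinned. Foxm1 was found in 48.7% of proliferating-like and 12.7% of osteoclast-like cells, while Acp5 was found in 49.2% of neutrophil-like cells.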

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

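Tests described below were chosen after the results were seen, except the comparison of R3′ libraries with the single-cell clusters and the share of cells with Lat at equal depth, which were written down beforehand.

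The synovial subsets departed from blood in opposite directions for 88 genes that were higher in R2′ and lower in R3′ than in R1, and for 69 genes that were lower in R2′ and higher in R3′. Both counts lie below the 646.82 and 689.54 of independent lists of these sizes. They became 41 and 37 without R1 replicate 1, 46 and 31 without R1 replicate 2, 41 and 32 without R1 replicate 3, 52 and 52 without R2′ replicate 1, 56 and 51 without R2′ replicate 2, 56 and 39 without R3′ replicate 2, 114 and 108 without R3′ replicate 3, and 182 and 183 with array weights. For all of the 88 and 69 genes the difference between R3′ and R2′ was itself called by limma. That outcome adds no support, since opposite differences from the same R1 libraries give a larger difference between R3′ and R2′. Among the named genes, the log2 difference of R3′ from R2′ was 4.28 for Birc5, 4.02 for Ube2c and -1.54 for Itgam. Birc5 and Ube2c fell from blood to R2′ (log2 -1.04 and -1.65) and rose to R3′, while Itgam rose in R2′ (1.15) and fell in R3′ (-0.39). The decrease of Ube2c in R2′ is fragile, as it was lost without R1 replicate 1 (-1.43), R1 replicate 2 (-1.71), R1 replicate 3 (-1.81), R2′ replicate 2 (-1.39) or R2′ replicate 3 (-1.28), with a pseudocount of 5 (-0.71), with array weights (-1.12) and without a filter. The decrease of Birc5 in R2′ (limma adjusted p 0.0479) was lost without R1 replicate 1 (-1.03), R1 replicate 2 (-1.16), R1 replicate 3 (-0.93), R2′ replicate 2 (-0.92), R2′ replicate 3 (-0.81) or R3′ replicate 2 (-1.04), with a pseudocount of 5 (-0.36), array weights (-0.69), quantile normalization (-1.03) or no trend, and without a filter. The decrease of Itgam in R3′ (limma adjusted p 0.0423) was lost without R1 replicate 1 (-0.38), R1 replicate 2 (-0.38), R1 replicate 3 (-0.40), R2′ replicate 1 or 2 (both -0.39), R3′ replicate 1 (-0.25) or R3′ replicate 2 (-0.37), with the 6 libraries alone and without a filter.

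Osteoclast genes differed widely between the R3′ libraries. The 7 osteoclast genes called higher in R3′ than in R2′ had a median log2 ratio of 2.56 between R3′ replicate 1 and R3′ replicate 3, and mitosis genes one of 1.17. The median of all 10958 genes was -0.00478, so a shift of all genes alike does not account for the ratio of the osteoclast genes. Because FPKM are already scaled to library size, that median cannot decide on depth or on the scaling before it. The macrophage maturation genes, whose median was -0.44, argue against dilution of R3′ replicate 3 by cells that lack these genes. They cannot decide on dilution by other macrophages, which would hold them too. The hypothesis that the libraries hold different shares of osteoclast-like cells was tested on 246 panel genes outside the osteoclast and proliferation lists. Across genes, which are not independent replicates, their ratio rose with the fold of the osteoclast-like cluster (Spearman rho 0.449, and 0.325 for R3′ replicate 2 against R3′ replicate 3), so a different share of such cells may explain the spread.

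Cells of the osteoclast-like cluster held transcripts of genes usually read as lymphoid or granulocytic, a signal no comparison of the report uses. These genes were picked after their values were seen. Trac was found in 8.68% of osteoclast-like cells against 0.136% of other cells, Lat in 48.7% against 2.01%, Cd5 in 39.4% against 1.32%, Ccr3 in 54.7% against 2.73% and Cd200 in 83.8% against 10.4%. T cells caught with osteoclast-like cells stay open as a source. Trac, Trbc2, Lck and Cd3d, abundant in T cells, had upper 95% limits of at most 11.2% of osteoclast-like cells, against a lower limit of 35.5% for the least found of Lat, Cd5, Ccr3 and Cd200, and 0 of 54 osteoclast-like cells with Trac held Cd3d, Cd3e or Cd3g (upper 95% limit 6.60%), but the library holds no T cell-like cluster to show how well the panel detects these genes in T cells, and 10 of the 20 cells with Cd3d were neutrophil-like. Greater depth is argued against, because the share with Lat was 26.3 times that of other cells at 1202 molecules per cell. Amplification of other transcripts by the panel primers stays open too, since in the bulk libraries, made without those primers, 2 of the 4 genes Lat, Cd5, Cd200 and Ccr3 were called higher in R3′ than in R2′ (Cd200 and Ccr3), Lat was not called, Cd5 was too low to be tested, and expression by osteoclast-like cells remains untested.

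Of 18 immediate early and heat shock genes, 14 were higher in R2′ than in blood and 16 in R3′, and of 19 cytokine and chemokine genes 18 in each, though neither list was called with an estimated correlation (limma camera adjusted p 0.27 and 0.257 in R2′, and 0.31 for both in R3′). The immediate early and heat shock list had a median log2 difference of 2.11 between R2′ and R1, led by Ier3 (4.80), Egr1 (5.17) and Fos (2.81), beside Cxcl2 and Cxcl1. Handling of the tissue and a response to inflammation cannot be told apart, because tissue and handling change together between blood and synovium.

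Other splits of the libraries tested the counts of calls. For genes, the real split called 4531 (R2′ against R1), 6470 (R3′ against R1) and 5103 (R3′ against R2′), and the highest of the other splits 0, 1 and 2. For lists it called 11, 15 and 11, and the highest others 9, 12 and 11. The preset list test thus called nearly as many lists in some splits that mixed both subsets, so the number of lists called says little by itself. In each case the 10 splits are too few for a share under 0.05; 1 of 10 splits gave as large a result, or 2 of 10 for the lists of R3′ against R2′. For R2′ against R1, where the replicate number is taken as a pairing, the 3 other splits that part all 3 pairs called 0 genes and 8 lists at most, and the 6 that part fewer called 0 genes and 9 lists at most. For the 3173 genes shared by both contrasts against R1, 1 of 100 drawn splits of the 9 libraries gave as many, the highest other being 2111. Splits that mix the subsets put their differences into the spread within groups, and the draws ignored the replicate number. They therefore give no level for the overlap of contrasts that each hold many called genes. The shared R1 libraries stay open as a source of part of the overlap.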

How the results depend on the processing

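Counts of called genes and lists stayed within 1.5 times the reported ones in 146 of 152 recomputed counts. Requiring a log2 difference of at least 1 left 1566, 2682 and 1590 genes for R2′ against R1, R3′ against R1 and R3′ against R2′, by its own construction. The estimated correlation left 0 lists in each contrast, where the preset one called 11, 15 and 11. Without 1 library the counts ran from 3567 to 4737, 5341 to 6649 and 3632 to 4960, the shared genes from 2485 to 3073, and the lists from 9 to 13, 14 to 16 and 9 to 12. Of all alternatives, array weights gave the most genes, 5337, 7660 and 6976.

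Foxm1 and Ctsk kept their direction and calls in every contrast and alternative run, Foxm1 in R3′ against R2′ between 1.18 and 3.36. Acp5 did so too except in R2′ against R1, where leaving out single libraries gave 1.74 to 2.01, lost without R1 replicate 2 or R2′ replicate 3. Atp6v0d2 was called in R2′ against R1 with a pseudocount of 0.1 (3.75), array weights (1.36) and the 6 libraries alone (1.31), and leaving out single libraries gave 1.15 to 1.49, called without R3′ replicate 1 or 3. Nfatc1 was called in R2′ against R1 with array weights (0.72) and the 6 libraries alone (0.73), with 0.67 to 0.82 when single libraries were left out, and in R3′ against R1 with array weights (0.99), with 0.42 to 1.21. In R3′ against R2′ its values ran from -0.31 to 0.48 without single libraries, called at 0.48 without R3′ replicate 3; a change of sign between values called in neither setting was not counted as a reversal. Itgb3 lost its call in R3′ against R1 with a pseudocount of 0.1 (-1.76), with -1.64 to -0.75 over the libraries left out, and in R3′ against R2′ without a filter (1.21), after quantile normalization (0.94) and with the 6 libraries alone (1.21), with 0.86 to 1.75. The causes were not tested. Leaving out R3′ replicate 3, which holds the least of these RNAs among the R3′ libraries, gave the highest differences of R3′ from R2′ for Acp5, Ctsk and Atp6v0d2, 3.79, 5.28 and 5.09.

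Of 5821 recomputed differences of named genes, 5653 kept their direction and side of the threshold, 77 gained and 91 lost a call, and none reversed. Of 75 pairs of list and contrast, 58 were the same under all alternatives except the estimated correlation. The osteoclast list in R2′ against R1 was called under several of them, the lipid-handling list in R3′ against R1 was lost with array weights, and the cytokine and non-classical monocyte lists in R3′ against R2′ were lost under several.

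With the replicate number as a block, limma called 4889, 6703 and 5416 genes, 4430, 6360 and 4964 of them also called without it. In R2′ against R1, where the number is taken as a pairing, the block called Atp6v0d2 (1.31), Uqcrc2 (-0.36), Ltf (-2.78) and the osteoclast list (0.92), and changed no other call of named genes and lists. For R3′ a pairing is left open. Only 2 of 3 pairs with R1 and 1 of 3 with R2′ correlated above 0.1 (0.0273 to 0.195), but each of the 9 libraries correlated best with one of its own number. There the block called the oxidative phosphorylation list (0.44), Csf1r (-0.28) and Cd2 (-1.10) in R3′ against R1, and Gbp2 (-1.28), S100a8 (1.30), Cd2 (-1.13), Il7r (-0.92) and Pdpn (-0.76) in R3′ against R2′, where the non-classical monocyte list (-0.90) was not called.

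In single cells, asking for at least 2 molecules lowered the shares to 2.57% for Foxm1, 62.9% for Acp5, 20.2% for Atp6v0d2, 60.2% for Ctsk, 7.74% for Itgb3 and 15.2% for Nfatc1, by construction. Leaving out the 5% of cells with the most molecules, chosen after seeing the data, gave 29.1% for Atp6v0d2, 78.4% for Ctsk, 9.06% for Itgb3 and 24.2% for Nfatc1. Without thinning, cells with Foxm1 held Ctsk in 90.2%, Itgb3 in 29.5%, Mki67 in 58.7% and Top2a in 59.7%, and cells without Foxm1 held Acp5 in 79.6%, Ctsk in 78.8%, Atp6v0d2 in 28.4%, Nfatc1 in 22.4%, Mki67 in 3.41% and Top2a in 5.46%, which narrows the contrast for Acp5, Ctsk, Atp6v0d2, Nfatc1, Mki67 and Top2a. The number of clusters was 7 at a Leiden resolution of 0.25 and 13 at 1. The osteoclast-like share was 13.9% and 7.77%, and the dendritic cell-like share 1.43% at 0.25. Leaving out doublets gave no values, as none was called, and a minimum of 500 molecules removed no cell. Thinning lowered the share with Foxm1 from 5.75% to 3.79% and that with Cx3cr1 from 8.996% to 5.08%.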

Other observations

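The chemokine gene Cxcl2 measured 20.5 FPKM in R1 replicate 1 against 1.19 and 0.719 FPKM in the other R1 libraries. Mir343, a small-RNA gene, was the highest gene of R2′ replicate 3 at 39194 FPKM, and small-RNA genes made up 8.93% of that library's FPKM against 2.86% to 4.84% in the other libraries. These values were picked after they were seen. Pf4, usually read as a platelet gene, reached 541 ± 94.3 FPKM in R3′ against 25.4 ± 11.6 FPKM in R1, while the platelet genes Ppbp and Itga2b were lower in R3′ than in R1, at log2 -2.37 and -2.75.

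In the single-cell library Cd79b, a B-cell gene, was found in 7.46% of cells and Il7r in 45.6%. In the bulk libraries Il7r measured 1.06 ± 0.857 FPKM in R1, 42.7 ± 11.4 FPKM in R2′ and 23.4 ± 12.3 FPKM in R3′.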
